A study of Mus musculus with 416 samples.

How the data were processed

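The deposited table gives each of the 416 striatum libraries a column of its own, over 46517 Ensembl gene IDs. Per the labels' protocols, brains were taken in a fixed morning window, the striatum was dissected after a short soak in a preserving solution, and total RNA was depleted of ribosomal RNA. Per the same labels a stranded kit was used, with 100 bp read pairs. The deposited values are estimated counts: 23.8% of them were not whole numbers, none was negative, and each column total lay within 1.4e-05 of a whole number. Neither the labels nor the file header name the aligner, the counting tool, the genome build or the annotation the authors used to make these estimated counts, and no normalization is stated. Columns were joined to libraries by the animal number in the label titles, with 0 columns left over.

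Gene names and chromosomes were taken from the GENCODE release M21 annotation by gene ID, which matched 46005 IDs (98.9%). As the build behind the deposited counts is not stated, no coordinates are given. Counts were rounded to whole numbers, which moved 0.005% of the total count. Total counts per library ran from 20331737 to 77458200 (median 43516282), and the mitochondrially encoded genes took 2.95% to 7.18% of them (median 4.61%).

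The groups are the 6 combinations of labelled sex and generation. The tests, the samples they use, the 40 gene lists, the rule for which genes are named, and most alternatives were fixed before the data were examined. Genes were kept with edgeR's filterByExpr over the 6 groups (minimum count 10), leaving 22968 genes, and 23549 IDs were not tested. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood, robust, legacy off) under R 4.3.3 with sex and generation as terms. The contrasts were female minus male and the 3 pairs of generations, with a test of 2 degrees of freedom for any generation difference and one for the sex by generation interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests are two-sided. CPM are counts scaled to a common library total with TMM factors, and log2 CPM carry a prior count of 2.

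The genes named are fixed by rule: the measured members of the Y list and the X-escape list, 10 autosomal genes per direction for sex with a mean log2 CPM of at least 1 and one sign in all generations, and 10 or 5 per direction for each pair of generations with one sign in both sexes. The 10 genes with the smallest interaction p, up to 4 members of each called list, and the 12 genes with the largest SD between libraries at a mean log2 CPM of at least 3 complete the rule. Gene models without a gene name were passed over. Not every gene that meets the rule is named in the text. Genes of the closing section that the rule does not name were chosen after their values were seen.

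The gene lists hold markers of striatal neuron classes, of neurons next to the striatum, of glia, vessels and ventricle lining, and genes of sex chromosomes, stress, clock, immune, receptor and housekeeping functions. Lists with at least 3 measured members were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each Benjamini-Hochberg adjusted over the lists, and over lists and contrasts together for generation. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. The 8 correlations between list scores used 100000 permutations, or 10000 in their alternatives. Shares of variance and SDs between libraries are descriptions without a test.

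The pipeline was tested on simulated data of 6000 genes with known folds. For the comparison of sexes it recovered 88%, 96%, 100% and 100% of genes changed by 1.1, 1.2, 1.5 and 2-fold, for generations 23 and 21 it recovered 82%, 94%, 96% and 100%, and for the interaction 50%, 80%, 96% and 98%. False calls among 5400 unchanged genes were 24, 34 and 17, which is above the nominal 5% of calls for each comparison. One first fit of the real counts was made before this simulation was written.

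A library was taken as against its label where Xist lay on the other side of 100 CPM, a limit set after the levels were seen. The planned rule named Xist and the Y genes together, and Xist alone was used because the Y genes are 0 in all libraries labelled female. Libraries of low total or low correlation had under 0.5 of the median total, or a median correlation with the others more than 4 scaled median absolute deviations (scale 1.4826) below the median. The scaled form was chosen after counts of such libraries had been seen, and the unscaled form was not run.

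Alternatives were DESeq2 1.42.0, edgeR's legacy fit, limma voom, RLE factors, no filter on low counts and a mean CPM of at least 1, total count and mitochondrial share as covariates, 5 residual principal components as covariates, a test against a fold of 1.2, each sex or generation alone, and fits without the libraries described above. Residual components are orthogonal to the labels and so remove spread only. Fits without both kinds of library together, and with the scores of 6 marker lists (cortical, thalamic, choroid plexus, septal and pallidal, oligodendrocyte, hypothalamic) as covariates, were added after seeing the data. Fits without male replicate 9, female replicate 34 or male replicate 26 of generation 21, without male replicate 29 of generation 22, and without male replicates 29 and 31 of generation 22 were added too, since these libraries moved named genes. For lists, the planned fit without doubtful libraries left out both kinds together. For the split counts by sex, genes off the Y chromosome were also counted alone, a count added after seeing the data. Labels were also shuffled over the libraries, in 100 splits for sex and for the interaction and 60 for generation. A run of 100 generation splits was made first and shortened to its first 60, with the verdicts for all 5 generation results the same. Tables were read with the data.table package (1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures drawn with matplotlib 3.10.9.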

Results

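The striatum is the input station of the basal ganglia, made up mostly of GABAergic spiny projection neurons that carry either the D1 or the D2 dopamine receptor. RNA of this tissue was sequenced after depletion of ribosomal RNA in 416 libraries from drug-naïve mice of the Diversity Outbred stock, in which every animal carries its own mixture of founder genomes. The labels give each library a sex and a breeding generation. There were 76, 60 and 72 libraries labelled female in generations 21, 22 and 23, and 74, 59 and 75 labelled male. The series was made to record expression in untreated animals, so sex and generation are the only comparisons its labels allow. Total counts per library ran from 20331737 to 77458200 with a median of 43516282. Group medians of the total lay between 40537880 (male, generation 23) and 45533432 (female, generation 21). Levels are given below as CPM, counts scaled to a common library total with TMM factors, as mean ± SD over libraries, and differences as log2 fold changes with their standard error.

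Transcripts of the X and Y chromosomes were compared with the labelled sex first. Xist, the noncoding RNA that coats the inactive X chromosome, lay at a median of 1860 CPM in most libraries labelled female and at 4.76 CPM in most labelled male. In 29 of the 416 libraries (6.97%) Xist went against the label. Of these, 15 labelled female had a median of 3.81 CPM (range 0.937 to 9.8), and 13 labelled male had a median of 1990 CPM (range 1540 to 2520). One further library labelled male lay between these levels, with Ddx3y at 42.3 and Kdm5d at 48.3 CPM, and is counted among the 29 by its Xist alone. The male-labelled libraries with high Xist held Ddx3y at a median of 0 CPM, Kdm5d at 2.27 CPM and Uty at 6.76 CPM (range 4.67 to 10.2), against 67.4, 67.5 and 66.4 CPM in the other libraries labelled male. Such libraries occurred in every group, from 3 in each sex of generation 23 to 7 in each sex of generation 22. All 1570 Y-chromosome genes of the table stood at exactly 0 in every library labelled female, while 1460 of them were above 0 in some library labelled male. Y genes were therefore treated as not measured in libraries labelled female, and no fold change is given for them. Their call between the labels, and that of their list, follows from these zeros.

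**Figure D1:**
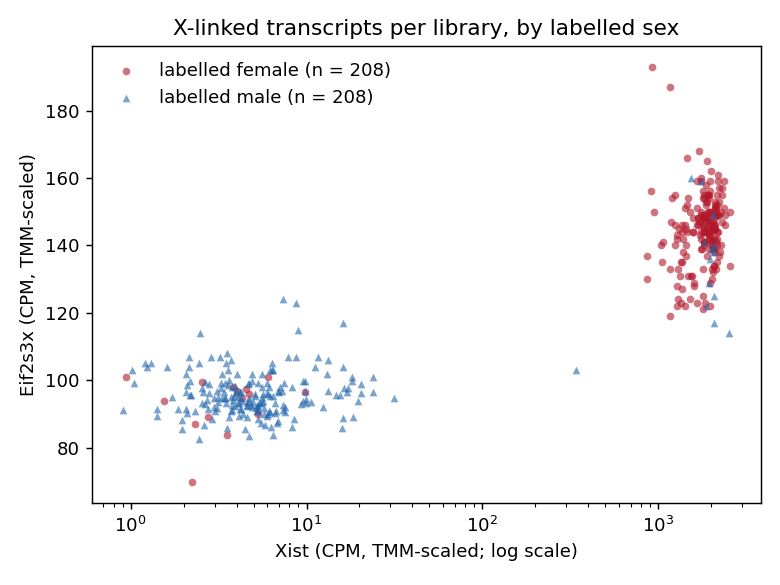
Xist (horizontal, CPM, log scale) against Eif2s3x (vertical, CPM) for each library, red circles for those labelled female and blue triangles for those labelled male. Of the 15 libraries labelled female with Xist at or below 9.8 CPM, all but female replicate 2 of generation 21 (Eif2s3x at 69.7 CPM) lie within the Eif2s3x range of libraries labelled male with low Xist. The 13 labelled male with Xist of at least 1540 CPM lie in or next to the cloud labelled female.

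The comparison of libraries labelled female and male asked which striatal genes differ between the sexes. Genes that escape X inactivation gave the clearest difference: 10 of the 11 measured members of that list were higher in libraries labelled female, and 10 when adjusted over the list alone. Eif2s3x (ENSMUSG00000035150), a subunit of the initiation factor that brings the first tRNA to the ribosome, was 1.43-fold higher (log2 0.52 ± 0.017 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.3e-102). The histone demethylase genes Kdm6a (ENSMUSG00000037369) and Kdm5c were 1.32-fold and 1.22-fold higher. Kdm6a stood at 62 ± 6.67 CPM in libraries labelled female (n = 76, 60 and 72 in generations 21, 22 and 23) and at 47.1 ± 5.62 CPM in those labelled male (n = 74, 59 and 75). The RNA helicase gene Ddx3x was 1.21-fold higher, at 271.5 ± 26.6 against 224.5 ± 22.2 CPM. The X-inactivation centre transcripts Jpx and Ftx were 1.22-fold and 1.11-fold higher, and 5530601H04Rik, Pbdc1 and Utp14a 1.18-fold, 1.14-fold and 1.07-fold. Xist averaged 1672 ± 575.9 CPM against 131.2 ± 482.2 CPM, a 14.2-fold difference that includes the libraries against their label. Without those 29 libraries its log2 difference was 8.19 in place of 3.83, a rise that follows from picking them by Xist itself. Usp9x, which encodes a deubiquitinase, did not differ (log2 0.0048 ± 0.011, adjusted p = 0.867).

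The 5 Y-list genes that passed the filter, Kdm5d, Uty, Ddx3y, Eif2s3y and Usp9y, have a value in libraries labelled male only. In those libraries Uty stood at 62.9 ± 16.2 CPM, Kdm5d at 62.4 ± 17, Ddx3y at 62 ± 18, Eif2s3y at 47 ± 13.3 and Usp9y at 0.635 ± 1.88. The X-escape list was also called by the competitive set test camera with an estimated correlation (Benjamini-Hochberg adjusted p = 3.89e-30).

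On the autosomes, differences between the sexes were small. Among genes higher in libraries labelled female, Ulk3 (ENSMUSG00000032308), a serine/threonine kinase gene, was 1.23-fold higher at 16.2 ± 1.42 against 13.1 ± 1.25 CPM (log2 0.30, edgeR adjusted p = 3.45e-74). Rmi1, whose product works with the BLM helicase in resolving recombination intermediates, was 1.14-fold higher. In the 15 libraries labelled female with low Xist the medians of Ulk3 and Rmi1 were 15.8 and 11.5 CPM, against 16.2 and 11.8 in the others labelled female and 13.1 and 10.5 in those labelled male with low Xist. In the 13 labelled male with high Xist they were 13.9 and 10.8 CPM. Both genes thus lay nearer to the level of the label than to that of Xist, so counting that differs by label is not excluded for them. Genes of matrix and metabolism in this direction were the collagen genes Col1a2 (1.15-fold) and Col1a1 (1.14-fold), Xdh of purine breakdown (1.17-fold), Pisd of phospholipid synthesis (1.17-fold) and Hif3a of the hypoxia response (1.2-fold). Cdhr1, a cadherin of photoreceptors, Synpo2, an actin-binding protein gene, and the protocadherin gene Pcdhb2 were 1.36-fold, 1.18-fold and 1.16-fold higher. Without female replicate 34 of generation 21 the log2 difference of Synpo2 was 0.164 in place of 0.237 and no longer passed (edgeR adjusted p = 0.0597). In the other direction Hsd11b1, whose enzyme regenerates active glucocorticoid, stood at 3.38 ± 1.63 CPM in libraries labelled female and 3.93 ± 1.73 CPM in those labelled male (log2 -0.22, edgeR adjusted p = 0.0116). The desmosomal cadherin gene Dsg1c stood at 2.72 ± 1.41 against 3.56 ± 1.85 CPM. Its median was 3.66 CPM in the 15 libraries labelled female with low Xist and 2.61 in the 13 labelled male with high Xist. The others labelled female held 2.49 CPM and those labelled male with low Xist 3.62, so Dsg1c lay nearer to the level of Xist. Also lower in libraries labelled female, by log2 values from -0.17 to -0.13, were Bche, a cholinesterase gene, Cfap54 of motile cilia, the secreted factor gene Ndnf, Zpbp, Zfp783, Emx2os, the protocadherin Pcdhga1 and the ribosomal protein gene Rps7. Each of these 20 genes had the same sign in all 3 generations, as the rule that names them requires. Pcdhga1 shares exons with its gene cluster, and Rps7 has processed copies, so their counts are uncertain. In the order of libraries given for Dsg1c, the medians of Rps7 were 52.6, 59.4, 55.9 and 58.5 CPM, nearer to the label. Those of Pcdhga1 were 11.5, 11, 10.3 and 11.8 CPM, nearer to Xist by little. Those of Pisd were 70.2, 72.6, 95.5 and 76.2 CPM, near the male level in both sets against the label. The other named autosomal genes were not compared in this way.

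In all, 656 of 22968 genes tested (2.86%) differed between the labelled sexes, of which 583 were autosomal, 50 were on the X and 16 on the Y chromosome, the last fixed by the zeros. Adjusted over the genes off the Y chromosome alone, 630 were called. Genes called with a fold above 1.2 made up 0.5% of those tested, and the median absolute log2 difference of the 656 was 0.082. X-linked genes were called more often than autosomal ones (6.55% against 2.65%, odds ratio 2.58, 95% interval 1.87 to 3.48, two-sided Fisher's exact test p = 2.78e-08). Of the called X genes 80% were higher in libraries labelled female, against 54.4% of the called autosomal genes (odds ratio 3.35, exact p = 0.000511). Without the 29 libraries against their label 1101 genes were called, among them 96.3% of the 656. Without the libraries of low total or low correlation the number was 1351.

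Of the 40 gene lists, camera with its preset correlation called 4 between the sexes: the X-escape list, the Y list with its zeros, and 2 more that were lost with an estimated correlation. Glucocorticoid response genes were higher in libraries labelled female (camera adjusted p = 0.000245, and adjusted p = 0.377 with an estimated correlation), although only Tsc22d3 among its 10 members passed the test over all genes and 5 passed when adjusted over the list alone. Tsc22d3, the leucine zipper gene induced by glucocorticoids, was 1.11-fold higher. Zbtb16 and Fkbp5 were 1.15-fold and 1.04-fold higher without passing over all genes (adjusted p = 0.0727 and 0.0852). Nuclear genes of oxidative phosphorylation were called as higher (camera adjusted p = 4.41e-07, and adjusted p = 0.972 with an estimated correlation), with 4 of 93 members past the test and 4 when adjusted over the list alone. Those 4 members, Uqcrb, Uqcr11, Atp5e and Uqcrq, were 1.03-fold to 1.04-fold higher. The other 36 lists were not called, with camera adjusted p from 0.0766 (microglia) to 0.976 (ependymal cells). They covered D1, D2 and pan-spiny projection neurons, cholinergic and GABA interneurons, cortical, thalamic, septal and pallidal, hypothalamic and dopaminergic neurons, astrocytes, oligodendrocytes and their precursors, endothelial, mural, choroid plexus and blood cells, and the neurogenic niche. Immediate early, clock, interferon, MHC class I, dopamine, opioid, endocannabinoid, glutamate, GABA, cholinergic receptor, sex steroid, heat shock, ribosomal, mitochondrially encoded and histone genes were the rest. No member of the dopamine signalling list (13 measured), the opioid list (7) or the immediate early list (15) passed over all genes or adjusted over the list alone.

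Generation 23 was compared with generation 21 to ask how the libraries of different breeding generations differ. The labels do not separate generation from cohort, date or batch of handling. Transcription factor genes of cortical excitatory neurons were higher in generation 23: Tbr1 (ENSMUSG00000035033) stood at 31.2 ± 25.9 CPM in generation 23 (n = 72 labelled female and 75 labelled male) and 10.3 ± 18.9 CPM in generation 21 (n = 76 and 74), a 3-fold difference (log2 1.59 ± 0.20 SE, edgeR adjusted p = 3.38e-13). Neurod2 and Neurod6 of the same neurons were 2.86-fold and 2.75-fold higher, and the orphan nuclear receptor gene Nr4a2 2.99-fold. Vxn, Cadps2 of dense-core vesicle release, the relaxin receptor gene Rxfp1, the synaptic organiser gene Cbln2 and Ipcef1 were 2.39-fold to 2.63-fold higher. All 9 had the same sign in both labelled sexes, as the rule that names them requires. Of the 10 measured members of the cortical excitatory list, 8 rose and 8 when adjusted over the list alone (camera adjusted p = 4.04e-05, and adjusted p = 0.557 with an estimated correlation). The cortical marker score, the mean log2 CPM of the list, was 1.65 ± 1.16, 2.02 ± 1.36 and 2.93 ± 1.23 in generations 21, 22 and 23. With the scores of 6 marker lists as covariates the difference in Vxn was 0.22 in place of 1.40, and that in Cadps2 0.17 in place of 1.39.

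**Figure D2:**
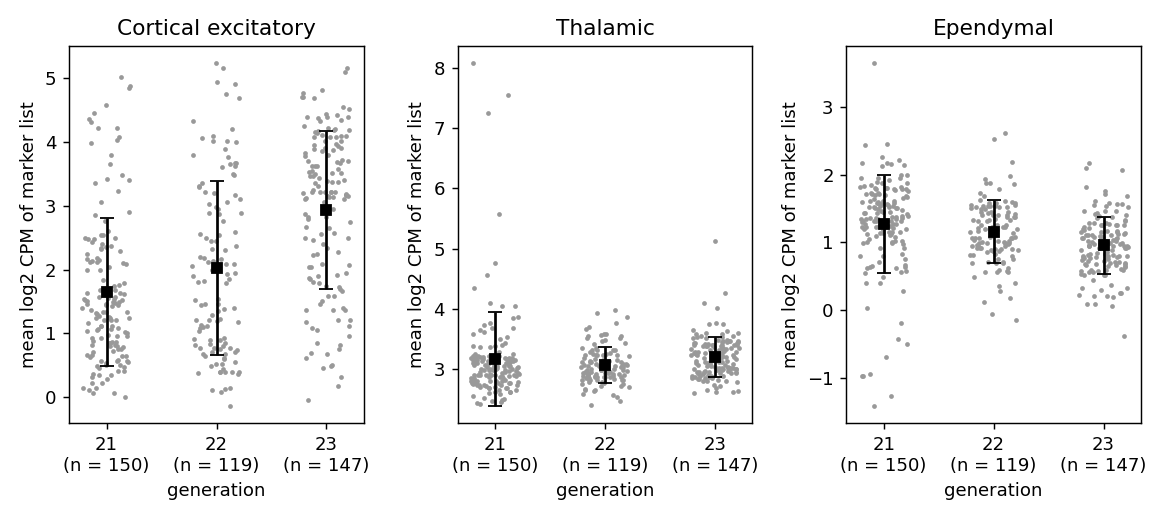
Marker list scores (mean log2 CPM of the list's members) for cortical excitatory neurons, thalamic neurons and ependymal cells, one grey point per library, in generations 21, 22 and 23. Black squares are means and bars SDs. The cortical score averages 1.65, 2.02 and 2.93, and the highest thalamic scores are in generation 21.

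Protein synthesis and chromatin genes moved the other way. Of 85 cytosolic ribosomal protein genes, 70 fell and 1 rose from generation 21 to 23, the same numbers when adjusted over the list alone (camera adjusted p = 1.66e-30, and adjusted p = 0.0453 with an estimated correlation). Rps28 had a log2 difference of -0.28 ± 0.014 and Rps10 of -0.23 ± 0.013. Of 61 replication-dependent histone genes, 59 fell, and 60 when adjusted over the list alone (camera adjusted p = 2.69e-18, and adjusted p = 0.176 with an estimated correlation). Hist2h3b averaged 4.42 ± 1.77 CPM in generation 21 and 2.72 ± 0.898 in generation 23, and Hist1h3b 3.37 ± 1.88 and 2.22 ± 0.937. Histone genes are near-identical copies, so counts of single members are uncertain. Of 93 nuclear genes of oxidative phosphorylation, 77 fell and 3 rose, or 79 and 3 adjusted over the list alone (camera adjusted p = 9.85e-16, and adjusted p = 0.515 with an estimated correlation). Ndufa13 of complex I had a log2 difference of -0.20 ± 0.014. Of 10 heat shock genes 6 rose, and 6 adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.786 with an estimated correlation). The chaperone gene Hsp90aa1 was 1.18-fold higher and Hspa1b, which is nearly identical to Hspa1a, 1.51-fold. Of the 11 X-escape genes 7 rose, and 7 adjusted over the list alone, with Usp9x and Pbdc1 1.11-fold and 1.1-fold higher (camera adjusted p = 0.00701, and adjusted p = 0.666 with an estimated correlation).

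Single genes lower in generation 23 included Prkcd (ENSMUSG00000021948), a kinase gene abundant in thalamic relay neurons, at 26.2 ± 138.7 CPM in generation 21 and 6.13 ± 7.69 in generation 23. Its level in generation 21 was set by a few libraries: female replicates 1 and 34 held 533.0 and 1350 CPM and male replicate 35 held 916.0 CPM, and these 3 libraries also stood apart from the rest by their correlation. Without the libraries of low total or low correlation its log2 difference was -0.15 in place of -2.06 and no longer passed (edgeR adjusted p = 0.139). Akap2, an anchoring protein gene of kinase A, and Mfrp, a membrane frizzled-related protein gene, turned sign without those libraries, from -0.87 to 0.054 and from -0.61 to 0.46. Without female replicate 34 of generation 21 alone Akap2 was at -0.53, and without male replicate 26 of that generation Mfrp was at -0.156 and no longer passed (adjusted p = 0.6). Hcn4, a channel gene of rhythmic firing, and Agt, the angiotensinogen gene of astrocytes, were lower by log2 values of -0.76 and -0.72, and by -0.34 and -0.39 without those libraries. The mitochondrial leucyl-tRNA synthetase gene Lars2 averaged 261.7 ± 1233 CPM in generation 21 and 102.8 ± 106.3 in generation 23 (log2 -1.22, edgeR adjusted p = 9.2e-09). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 had log2 differences of -0.85 and -0.68. Ribosomal RNA was depleted from these libraries, so what depletion left of it is not told apart from expression here. Male replicate 9 of generation 21 alone held 14720 CPM of Lars2, 5500 of mt-Rnr1 and 12510 of mt-Rnr2, and without it the log2 differences were -0.669, -0.538 and -0.36 (edgeR adjusted p = 0.000256, 0.00284 and 0.00744). In all, 13401 genes (58.3%) differed between generations 23 and 21, 5918 higher and 7483 lower, and 2215 of them had a fold above 1.2. Their median absolute log2 difference was 0.133.

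Generation 22 was compared with the same generation 21 libraries. Neurod6, Neurod2, Nr4a2, Tbr1 and Vxn were 2.07-fold, 1.89-fold, 1.74-fold, 1.66-fold and 1.64-fold higher in generation 22 (n = 60 and 59). The cortical list was not called (6 members higher and 1 lower, or 7 and 1 adjusted over the list alone, camera adjusted p = 0.34). Ribosomal protein genes fell in 70 and rose in 2 of 85 cases, or 71 and 2 adjusted over the list alone (camera adjusted p = 1.5e-36, and adjusted p = 0.0261 with an estimated correlation), with Rpl8 at log2 -0.20 ± 0.014 and Rpl14 at -0.19 ± 0.014. Oxidative phosphorylation genes fell in 77 and rose in 3 of 93 cases, or 78 and 3 adjusted over the list alone (camera adjusted p = 2.51e-25, and adjusted p = 0.227 with an estimated correlation). Histone genes fell in 49 of 61 cases, or 52 adjusted over the list alone (camera adjusted p = 5.38e-11, and adjusted p = 0.515 with an estimated correlation). X-escape genes rose in 8 of 11 cases, and 8 adjusted over the list alone (camera adjusted p = 0.00302, and adjusted p = 0.608 with an estimated correlation). Single genes lower in generation 22 were Prkcd (log2 -2.16), Akap2 (-0.89), the neurotrophic factor receptor gene Ret (-0.69), the G-protein signalling regulator gene Rgs16 (-0.69) and Agt (-0.64). Without the libraries of low total or low correlation these were -0.33, 0.020, -0.20, -0.14 and -0.36, and Akap2 and Rgs16 no longer passed (edgeR adjusted p = 0.874 and 0.0643). Without female replicate 34 of generation 21 alone Akap2 was at -0.543. In all, 10706 genes (46.6%) differed, 5068 higher and 5638 lower in generation 22.

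Between generations 23 and 22, cortical genes were again among the genes named by rule. Cbln2, Tbr1, Nr4a2 and Car10 were 1.86-fold, 1.80-fold, 1.72-fold and 1.69-fold higher in generation 23, and 7 of 10 cortical list members rose, with 7 adjusted over the list alone (camera adjusted p = 2.84e-12, and adjusted p = 0.118 with an estimated correlation). Heat shock genes rose in 9 of 10 cases, and 9 adjusted over the list alone, with Hspa1a 1.40-fold higher (camera adjusted p = 1.6e-07, and adjusted p = 0.297 with an estimated correlation). Nicotinic and muscarinic receptor genes rose in 6 and fell in 1 of 11 cases, also adjusted over the list alone, among them Chrm2 and Chrm3 at 1.25-fold and 1.26-fold, although Chrm3 had a log2 difference of -0.021 with 6 marker scores as covariates (camera adjusted p = 0.00121, and adjusted p = 0.176 with an estimated correlation). Glucocorticoid response genes rose in 3 of 10 cases, and 3 adjusted over the list alone, with Zbtb16 1.26-fold higher (camera adjusted p = 0.0175, and adjusted p = 0.728 with an estimated correlation). Pan-spiny projection neuron markers fell in 8 of 14 cases, or 10 adjusted over the list alone. Among them the adenylate cyclase gene Adcy5 and the G-protein subunit gene Gng7 had log2 differences of -0.14 ± 0.034 and -0.12 ± 0.038 (camera adjusted p = 0.00372, and adjusted p = 0.800 with an estimated correlation). The cortical marker score was higher in the same libraries, and with 6 marker scores as covariates the difference in Gng7 was 0.013 and the list moved the other way (camera adjusted p = 0.0269).

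Other lists also fell from generation 22 to 23. Histone genes fell in 30 of 61 cases, or 37 adjusted over the list alone, with Hist1h1d at log2 -0.22 ± 0.037 (camera adjusted p = 2.31e-12, and adjusted p = 0.410 with an estimated correlation). Ependymal markers fell in 4 of 7 cases, or 6 adjusted over the list alone, with Tmem212 at -0.24 ± 0.082 (camera adjusted p = 0.0145, and adjusted p = 0.739 with an estimated correlation). Negative-limb and output genes of the circadian clock fell in 6 of 10 cases, and 6 adjusted over the list alone (camera adjusted p = 0.00227, and adjusted p = 0.650 with an estimated correlation). The clock output gene Dbp averaged 90.5 ± 17.3 CPM in generation 22 and 79.5 ± 13.9 in generation 23. Ribosomal protein genes fell in 11 of 85 cases, or 6 adjusted over the list alone (camera adjusted p = 0.0273, and adjusted p = 0.866 with an estimated correlation). Single genes lower in generation 23 were Lars2 (log2 -0.75), the small nucleolar RNA Rnu3a (-0.40), the protocadherin gene Pcdh20 (-0.38) and the cilia genes Dnah7a (-0.33) and Spag16 (-0.33). Without male replicate 29 of generation 22 Pcdh20 was at -0.203, and without male replicates 29 and 31 of that generation at -0.0594 and no longer passed (edgeR adjusted p = 0.465). In all, 4171 genes (18.2%) differed, 1959 higher and 2212 lower in generation 23. With 6 marker list scores as covariates 2019 genes were called, and these held 27.8% of the 4171.

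Over the 3 generations together, 14643 genes (63.8%) differed by the test with 2 degrees of freedom. The generation lists that were not called by camera had adjusted p from 0.0657 (oligodendrocyte precursors) to 0.990 for generations 22 and 21, from 0.0593 (ependymal cells, cholinergic receptors) to 0.990 for 23 and 21, and from 0.0593 (D1 neurons, GABA interneurons) to 0.995 for 23 and 22. With 6 marker scores as covariates, 7 called generation lists no longer passed. These were heat shock genes for 23 and 21 (camera adjusted p = 0.0993), and for 23 and 22 ependymal (0.21), negative-limb clock (0.333), cholinergic receptor (0.879) and ribosomal protein genes (0.497). The cortical list in both comparisons (0.952 and 0.928) is itself one of the covariates. Among lists not called, the median, the mean and the test did not always share a sign. Thalamic markers from generation 21 to 23, for example, had a median of -0.44, a mean of -0.65 and an upward test (camera adjusted p = 0.990). The test of whether the sex difference depends on generation called 74 genes (0.322%), and 29 without male replicates 29 and 31 of generation 22.

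Scores of cell classes moved together across animals after the mean of each sex and generation was removed. Libraries with more of the D1 markers also had more of the D2 markers, with Pearson's r = 0.927 and Spearman's rho = 0.640 over 416 libraries, and r = 0.829 without the 2 libraries farthest from the median D1 score (r = 0.953, 0.891 and 0.811 within generations 21, 22 and 23). Pan-spiny scores fell as cortical scores rose (r = -0.510, rho = -0.733, -0.716 without 2 libraries, and -0.326, -0.700 and -0.822 within generations). Choroid plexus and ependymal scores rose together (r = 0.431, rho = 0.389, 0.399 without 2 libraries, and 0.349, 0.535 and 0.529 within generations). For these 3 pairs both two-sided permutation p values were 1e-05, the smallest that 100000 permutations can give (2.67e-05 after Benjamini-Hochberg adjustment over 8 pairs).

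**Figure D3:**
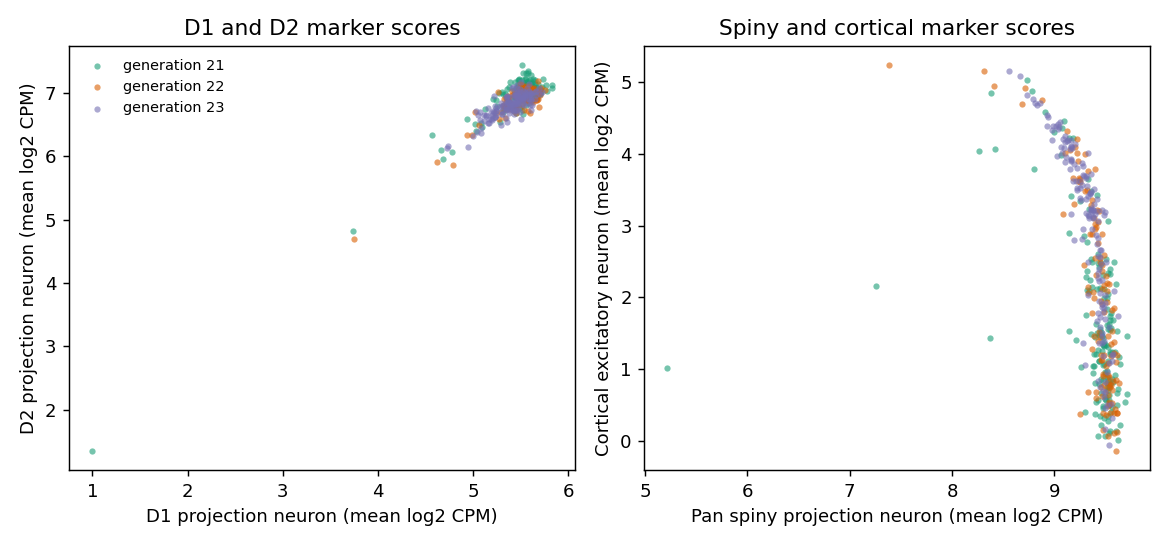
Marker list scores (mean log2 CPM) per library, coloured by generation: D1 against D2 projection neurons (left) and pan-spiny against cortical excitatory neurons (right). The D1 and D2 scores rise together, and the spiny score falls where the cortical score is high. The points show scores as they are, while r (0.927 and -0.510) was computed after the mean of each sex and generation was removed.

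The other 5 pairs were weaker. Astrocyte and microglia scores rose together (r = 0.137, permutation p = 0.00543, adjusted p = 0.00724, rho = 0.170 with p = 0.00037 and adjusted p = 0.000592, r = 0.192 without 2 libraries). Within generations r was 0.036, 0.172 and 0.267. Positive-limb and negative-limb clock scores ran opposite (r = -0.153, permutation p = 0.00176, adjusted p = 0.00282, rho = -0.173 with p = 0.00051 and adjusted p = 0.00068, r = -0.179 without 2 libraries). Within generations r was -0.077, -0.182 and -0.233. Spiny and oligodendrocyte scores ran opposite (r = -0.192, permutation p = 0.00028, adjusted p = 0.00056, rho = -0.210 with p = 2e-05 and adjusted p = 4e-05, r = -0.090 without 2 libraries). Within generations r was -0.279, -0.052 and -0.088. Immediate early and glucocorticoid response scores passed by Pearson's r alone (r = 0.112, permutation p = 0.0223, adjusted p = 0.0228, rho = 0.087 with p = 0.0786 and adjusted p = 0.0898, r = 0.132 without 2 libraries). Within generations r was 0.159, 0.101 and 0.061. The relation of spiny to septal and pallidal scores rested on 2 libraries (r = -0.116, permutation p = 0.0228, adjusted p = 0.0228, r = 0.045 without them, rho = 0.061 with p = 0.216 and adjusted p = 0.216). Within generations r was -0.352, 0.217 and 0.361.

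Most of the variance lay outside both labels. In a median gene the labelled sex accounted for 0.207% of the variance of log2 CPM, generation for 2.55% and the rest, in which animal, dissection, handling and counting are not separated, for 96.9%. The median SD between libraries, 1 per animal, after sex and generation was 0.295 on the log2 scale. Among genes with a mean log2 CPM of at least 3, the signal recognition particle RNA Rn7s1 had the largest SD (5.09, with 10th and 90th percentiles of 31.6 and 32020 CPM). The mitochondrial gene mt-Co2 (2.90), the choroid plexus transport protein gene Ttr (2.83, 2.98 to 533.3 CPM), Rpl37rt (2.46), the mitochondrial gene mt-Nd4l (2.35) and Xist (2.35) followed. The vesicular glutamate transporter gene Slc17a7 of cortical neurons (1.93, 4.68 to 210.9 CPM), Tbr1 (1.82) and Cdhr1 (1.55) were also among the 12, as were Pgk1-rs7 (2.23), a gene copy of Rnu3a (1.65) and Rn7s6 (1.51). Rpl37rt and Pgk1-rs7 are retrotransposed copies, so their reads can come from the parent gene.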

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

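The tests in this part were planned, with exceptions. The fits without both kinds of doubtful library, without named libraries and with marker list scores were chosen only after the result was seen. The sex difference depended on generation for 74 genes by edgeR's interaction test. Of the 100 splits of the libraries with shuffled labels, 30 gave at least as many genes, the real one included, and the highest other split gave 505, so chance cannot be excluded. That split called several times the real number, and the reason was not identified. Without both kinds of doubtful library 14 genes were called, and 12 of these were among the 74. limma voom called 0 genes, with 1390 at an unadjusted p under 0.05, and DESeq2 called 32.

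Lars2 and both mitochondrial ribosomal RNAs differed in their sex difference between generations (edgeR adjusted p = 0.0249 for Lars2, 0.028 for mt-Rnr1 and 0.00498 for mt-Rnr2). The female minus male log2 differences in generations 21, 22 and 23 were -1.44, -0.22 and 0.15 for Lars2, -1.29, -0.083 and 0.14 for mt-Rnr1, and -1.05, -0.13 and 0.26 for mt-Rnr2. Without both kinds of doubtful library none of these passed (adjusted p = 0.23, 0.34 and 0.0725), nor did any without male replicate 9 of generation 21, the library with the highest level of all 3 (adjusted p = 0.842, 0.572 and 0.518).

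The remaining genes singled out by the interaction test were lower in libraries labelled female in generation 22, higher in them in generation 21 (log2 0.137 to 1.35) and between -0.7 and 0.116 in generation 23. Their female minus male log2 difference in generation 22 was -2.76 for the LIM homeobox gene Lhx9 (edgeR adjusted p = 7.09e-08), -2.78 for the sodium-proton exchanger gene Slc9a4 (5.36e-07), -1.46 for the transcription factor gene Bhlhe22 (9.52e-07) and -2.34 for the lactase gene Lct (5.46e-05). It was -0.88 for the calcium-binding protein gene Cabp7 (0.000165), -1.19 for Fam19a1 (0.000165), -1.65 for the transcription factor gene Neurod1 (0.000184), -0.99 for the complement-related gene C1ql2 (0.000241), -0.82 for Shisa6 (0.000351) and -0.63 for Pcdh20 (0.000561). In limma voom the adjusted p of these 10 genes lay between 0.82 and 0.918. Without both kinds of doubtful library none of the 9 still tested passed (adjusted p from 0.439 for Neurod1 to 0.994 for Cabp7), and Slc9a4 was not tested there. In generation 22 male replicates 29 and 31 held the 2 highest levels of all libraries for 9 of the 10 genes, and 2 of the 3 highest for Lhx9. Cabp7 stood at 104.5 and 96.93 CPM in them, against a median of 3.91. Without these 2 libraries 29 genes were called by the interaction test, and of the 10 only Bhlhe22 passed (adjusted p = 0.0361, the others 0.142 to 0.939). Replicates 29 and 31 had cortical scores of 5.233 and 4.942 (generation 22, 2.02 ± 1.36) and pan-spiny scores of 7.385 and 8.409. Replicate 29 is also among the libraries against their label, with Xist at 1540 CPM and Ddx3y at 0 CPM. Its level thus counts as male in the sex difference although its Xist is high. With 6 marker list scores as covariates 15 genes were called by the interaction test, 13 of them among the 74. Without the libraries against their label 42 genes were called, 36 of them among the 74. Fewer calls thus remained in both fits, but no test was made of whether these traits account for the interaction calls.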

How the results depend on the processing

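The fits without both kinds of doubtful library, without single named libraries or a pair of them, and with 6 marker list scores as covariates were chosen only after the results were seen; the other alternatives, and the fit without both kinds for lists, were planned. The count of genes that differ among the 3 generations stayed within 1.5 times of 14643 under each alternative (10332 to 15501 genes). The number of called correlations also stayed within 1.5 times. The median shares of variance and the median SD between libraries moved by less than 1 SD over genes. That limit does not bound their ratio. For sex (2.86%), the share called was 9.06% with 5 residual components as covariates, 4.78% without libraries whose Xist goes against the label, 5.90% without libraries of low total or low correlation, 7.93% without both and 4.35% with marker scores. It was 0.289%, 0.243% and 0.528% within generations 21, 22 and 23, where fewer libraries were fitted, and 0.170% against a fold of at least 1.2. Against that fold, which the test's own construction makes stricter, the shares were 0.705% for generations 22 and 21, 2.35% for 23 and 21 and 0.139% for 23 and 22. Within libraries labelled male 28.6% differed between generations 22 and 21. For generations 23 and 22 the share was 8.79% with marker scores, 4.08% within libraries labelled female and 4.58% within those labelled male. The interaction (0.322%) was the least stable: 0.139% with DESeq2, 0 with limma voom (1390 genes at an unadjusted p under 0.05), 0.286% with no filter on low counts, 0.175% at a mean CPM of at least 1, 0.192% with total and mitochondrial share, 2% with 5 residual components, 0.182% without libraries against the label, 0.0917% without libraries of low total or low correlation, 0.061% without both, 0.0653% with marker scores, 0.126% without male replicates 29 and 31 of generation 22, and 0.191% to 0.348% on leaving out 1 of 4 single libraries. Of the lists, 2 for sex and 2 for generation were called with an estimated correlation in place of 4 and 19, 52 for generation by fry, and 7 for sex with marker scores. Reversals were few. Usp9x between the sexes, not called in any fit, was -0.0011 with marker scores and -0.0014 within generation 23. Akap2 was 0.054, 0.073 and 0.015 for generations 23 and 21, and 0.020, 0.050 and 0.108 for 22 and 21, without libraries of low total or low correlation, without both kinds and with marker scores. Mfrp for 23 and 21 was 0.455, 0.461 and 0.042 in the same order. With marker scores the differences between generations 23 and 22 were 0.013 for Gng7, 0.018 for Pde1b, 0.0084 for Rasd2 and -0.021 for Chrm3, and the pan-spiny list was called in the other direction (camera adjusted p = 0.0269). The correlation of spiny with septal and pallidal scores was 0.016 with mean z scores and 0.121 without both kinds of doubtful library. Over all comparisons of single genes, lists and correlations 87.1% (3065) kept their direction and their side of the threshold. A further 11.8% no longer passed, 0.568% newly passed and 0.511% were the reversals above. For interaction genes, and for lists under camera with an estimated correlation or fry, only the side of the threshold was compared. A reversal there would not be counted. Apart from the smaller groups and the stricter fold, the cause was not tested. With at least 20331737 counts per library, simulation recovered 82% of 1.1-fold changes for generations 23 and 21. It drew genes independently and held no libraries against their label, so recovery in the real libraries can differ.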

Other observations

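The tests of mislabelled and mixed libraries, of the dilution by wrong labels, the relations between single genes, the fits with marker scores, and the splits counted off the Y chromosome were chosen only after the results were seen; the other tests in this part were written before. Gene groups that camera did not call between generations 23 and 21 still moved on balance by fry, which does not compare a list with other genes. Fry called 52 list tests between generations against 19 by camera, and the 4 given here were chosen after their values were seen. Of all genes tested, 25.77% were higher and 32.58% lower in generation 23 than in 21. For generation 22 against 21 these shares were 22.07% and 24.55%. Many lists can pass such a test for that reason alone, and lists called by fry were not counted under shuffled labels. Blood markers fell in 5 of 6 cases, and 5 adjusted over the list alone (fry adjusted p = 7.45e-09, camera adjusted p = 0.132). GABA system genes rose in 11 and fell in 5 of 18 cases, and the same adjusted over the list alone (fry adjusted p = 1e-07, camera adjusted p = 0.204). Microglial markers fell in 8 and rose in 1 of 10 cases, and the same adjusted over the list alone (fry adjusted p = 9.67e-05, camera adjusted p = 0.204). From generation 21 to 22, MHC class I genes fell in 8 and rose in 1 of 10 cases, and the same adjusted over the list alone (fry adjusted p = 0.000866, camera adjusted p = 0.160), while fry did not call them for 23 and 21 (adjusted p = 0.189) or for 23 and 22, where 2 rose and 0 fell (adjusted p = 0.0625).

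Some transcripts moved together across animals, among 5 relations computed after the group means were removed. Lars2 followed mt-Rnr1 (r = 0.925, rho = 0.914, r = 0.918 without 2 libraries, 0.915, 0.966 and 0.896 within generations 21, 22 and 23) and mt-Rnr2 (r = 0.843, rho = 0.761, r = 0.824 without 2 libraries, 0.864, 0.893 and 0.748 within generations). Ribosomal RNA had been depleted, and whether the relations of Lars2 reflect what depletion left was not tested. The choroid plexus gene Ttr followed Mfrp (r = 0.923, rho = 0.561, r = 0.920 without 2 libraries, 0.906, 0.935 and 0.930 within generations). Xdh followed Hif3a, which both were higher in libraries labelled female (r = 0.636, rho = 0.626, r = 0.617 without 2 libraries, 0.579, 0.586 and 0.731 within generations). For these 4 relations both permutation p values were 1e-05, the smallest that 100000 permutations can give (1.25e-05 after Benjamini-Hochberg adjustment over the 5). The mitochondrial genes mt-Co2 and mt-Nd4l ran weakly opposite by Pearson's r alone (r = -0.105, permutation p = 0.0311, adjusted p = 0.0311, rho = -0.040 with p = 0.409 and adjusted p = 0.409, r = -0.100 without 2 libraries, -0.027, -0.193 and -0.105 within generations).

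By correlation 28 libraries stood apart from the rest, 10 of them in the female group of generation 21, and female replicate 27 of generation 23 had under 0.5 of the median total (20331737 counts). Together with the 29 libraries against their label these made 54 libraries. Among those 10, female replicate 34 of generation 21 held Drd1 at 1.52 CPM and Prkcd at 1350 CPM. The closest pair among all libraries was female replicate 50 and male replicate 60 of generation 21 (correlation 0.9898, next pair 0.9845). Their Xist levels were 1970 and 1870 CPM.

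The first pattern is the 29 libraries whose Xist goes against the label. A mixture of tissues from both sexes was argued against for most of the 14 labelled male, since Xist lay between 10% and 90% of the median of libraries labelled female in 14.3% of them. For the 15 labelled female it was not tested, as the limit that picked them keeps Xist below that range. Wrong sex labels may account for most of them: the medians of Kdm6a, Eif2s3x, Kdm5c and Ddx3x lay nearer to the other label in 8 of 8 comparisons. Animals with a single X chromosome among the 15 libraries labelled female stay open, as the Y genes hold no value there. The 29 libraries were unequally spread over generations by a two-sided Fisher's exact test (p = 0.0477), which takes each library as independent. Those labelled female and male numbered 5 and 4 in generation 21, 7 and 7 in generation 22, and 3 and 3 in generation 23. With numbers so close in both labels, independence is doubtful, and that p value may be too small.

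The second pattern is the set of autosomal genes that differ between the labelled sexes. Wrong labels may dilute them: genes called with the 29 libraries included had a median absolute log2 difference 1.11 times as large without them. Counting that left Y genes out of libraries labelled female could also move shared reads to autosomal copies. Over the 998 autosomal genes called without the 29 libraries, that explanation cannot be told apart from a difference of sex. The slope of their level in the libraries against the label was 0.354 (95% interval 0.233 to 0.487). On this scale 1 is the level of the own label and 0 that of the other. The slope was 0.459 for the label female and 0.248 for male. Over both it was 0.255 without the 4 genes of largest difference relative to the spread between libraries. The 998 genes were picked, and both end levels taken, from the same other libraries. Noise shared by these steps can raise the slope above 0, by an amount that was not estimated. Ulk3 and Rmi1 were seen to keep their label's level and so are no test of this. They kept shares of 0.805 and 0.701 of it, on the same scale. The gene models Gm26748 and Gm37985, seen in the same way, kept 1.07 and 0.998. These are the 4 genes of largest difference relative to the spread between libraries, and all 4 had a share over 0.5.

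The third pattern is the difference between generations 23 and 21 with cortical markers higher in generation 23. Tissue next to the striatum in the dissection was argued against as the whole cause, since 91.3% as many genes were called with 6 marker list scores as covariates, and depth or mitochondrial share likewise, with 98.3% as many. Part of the pattern may still come from such tissue: 75.7% of the calls were shared with that fit, Vxn fell from a log2 difference of 1.40 to 0.22, and all 10 cortical markers passed the filter in these striatum libraries, with Slc17a7 at 48.9 ± 85.2, 67 ± 102.1 and 110.5 ± 92.6 CPM in generations 21, 22 and 23. The verdict on tissue covers generations 23 and 21 only. Between generations 23 and 22, 2019 genes were called with the same covariates in place of 4171, and 27.8% of the 4171 were kept. Such tissue is therefore not argued against for generations 23 and 22. Generation as a biological difference, and cohort or handling, were not tested apart, as the labels do not separate them.

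Other splits of the libraries with shuffled labels were counted for each result. For sex only the real one of 100 splits gave as many as 656 genes, and 1 other split gave 649. With the genes off the Y chromosome alone 2 of 100 splits, the real one included, gave at least as many as the real 630, so chance can be excluded at that share only. The highest other split gave 649, more than the labels did, so a count of this size can also arise from shuffled labels. For generation 1 of 60 splits gave as many, so chance can be excluded: 14643 genes against 591 in the highest other split for any difference, 10706 against 725 for generations 22 and 21, 13401 against 651 for 23 and 21, and 4171 against 1129 for 23 and 22. For lists chance cannot be excluded as the source of the number called by camera with its preset correlation: 89 of 100 splits gave at least as many as the 4 lists for sex, with 21 in the highest other, and 43 of 60 gave at least as many as the 19 for generation, with 36 in the highest other.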
